A study of Mus musculus with 16 samples.

How the data were processed

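Total RNA from small regions of CD1 mouse embryos was sequenced in 16 libraries, 4 at E8.5, 4 at E9.5 and 8 at E10.5, where E gives the embryonic day. Per the labels, RNA was purified with a ZR RNA MicroPrep kit (Zymo) and read as 50-base single-end reads on an Illumina HiSeq. The processing notes of the authors name Bowtie, TopHat, TopHat2 and Cufflinks and the mouse build mm9. Versions, the annotation and any filter on genes are not given in the sources used here. The labels state read depths above 40000000. No read or count total per library was given, so the exact depth of each is unknown and no counting interval or detection limit was computed.

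The deposited values were a ratio, which was worked out from the values themselves. Each of the 15876 genes had a median of 1 over the 16 libraries, within 1e-06, so every gene had been divided by its own median by the authors. In 8794 genes at least 2 libraries shared the lowest value, and 5559 genes were at exactly 1 in 9 or more libraries, which points to a floor to which low values were raised before the division. The unit before the division is not stated. Cufflinks writes FPKM, and the thresholds had been written for FPKM before the data were examined. Ratios stopped at 0.01, which held for 25 values of 6 genes. A ratio compares libraries for 1 gene, and it does not compare genes. A level was therefore defined as a value divided by the lowest value of the gene over the 16 libraries. In 8788 genes with a shared lowest value the level is a multiple of the floor. In the other 7082 genes, called never-tied here, no 2 libraries share the lowest value, and the level is a lower bound. The thresholds in FPKM were applied to levels. Between single libraries, a library at the floor of a gene gives the fold against it only as a lower limit, written "at least". In 3337 genes the highest value was under 2 times the lowest, for which no cause was tested, and differences among values raised to a floor cannot be seen. The symbols of 194 genes stand on more than 1 row, and each row was kept apart by its Ensembl identifier.

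Libraries were grouped by stage and tissue as the labels give them. Where the labels or the markers leave doubt on the tissue, a library is called the library labelled with its name. Each region and stage has 1 library. In 12 comparisons of single libraries, a gene was counted when it differed by 2-fold or more and had a level of at least 5 in the higher library, and no p-value can be given. The shift between 2 libraries was the median log2 ratio of never-tied genes, in place of genes at 5 FPKM or more in both, which ratios cannot give. Counts are given as deposited and relative to the median gene, that is after the shift was removed. Folds of genes and medians of lists are relative to the median gene. Genes in the same direction in 2 comparisons were counted beside the number given by chance, the product of both counts over the genes eligible in both. A gene was called enriched in a library when its level was at least 5 and its value at least 4-fold above each other library.

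Comparisons of tissue classes used limma (3.58.1, R 4.3.3) with a mean-variance trend on log2 ratios, for genes above the floor in at least 3 libraries of the fit. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 and a fold of at least 2. Values at the floor entered the fits as they stand, so a fitted fold that includes them depends on the floor. For a gene at the floor in each library of a class no fitted fold is given, only the fold of the lowest library of the other class over that floor, relative to the median gene unless marked as deposited. E10.5 neural epithelium (3 libraries) was compared with the E10.5 nasal prominences and arches (4 libraries), and with E8.5 neural epithelium (3 libraries). The libraries of a class are different regions, so the test measures spread between regions and not between repeats. The planned logarithm of FPKM plus 1 could not be formed from ratios, so its pseudocount of 1 and the alternative of 0.1 were not run.

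A set of 30 gene lists with 290 genes was fixed before the data were examined, of which 237 genes were measured. They cover floor plate, hedgehog targets, neural progenitor, neuronal differentiation, forebrain, midbrain and hindbrain, dorsal neural, ventral telencephalon, cranial mesoderm, neural crest, facial mesenchyme, distal arch (the Dlx5 and Dlx6 program), maxillary program, nasal prominence, olfactory placode, surface epithelium, secreted ligands, extracellular matrix, chondrogenic and osteogenic, heterochronic, proliferation, muscle and heart, endothelium, erythroid, macrophage, visceral endoderm, notochord, sensory ganglion, stress and immediate early, and sex-linked genes. Of the visceral endoderm list 0 of 6 genes were measured, of the macrophage list 1 of 8 (Fcer1g) and of the notochord list 1 of 4 (Nog). For single libraries, members were counted as higher, lower or neither, and the median log2 ratio of the members above the floor was ranked among 10000 random lists of equal size matched on level. That percentile describes the list among genes and is no test across embryos. It was left out where fewer than 3 members were above the floor. For tissue classes, members were counted with p adjusted over all genes and adjusted over the list alone, and the mean of the list was compared by a two-sided exact permutation of the library labels.

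Named genes were chosen by a rule written before the data were examined. It takes the members of the fixed lists, the 10 genes with the largest ratio per direction in each comparison of single libraries, the 10 largest per direction past the threshold in each limma comparison among genes whose libraries do not overlap between classes, the 5 most enriched genes per library, and the 10 largest per direction shared by both arch comparisons. Some genes the rule names are not used here. Clone names, predicted names and small RNA genes were passed over. Histone genes, ribosomal and respiratory genes, and genes named with levels as markers of doubtful labels were chosen after the values were seen.

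Alternatives planned beforehand were a lower and a higher level threshold (1 and 20), scaling to the median gene, no filter or a stricter filter for limma, limma without the trend, the library labelled central in place of the dorsal control, and leaving out each library of a class. Alternatives added after seeing the data were the removal of a trend with transcript GC content, counting never-tied genes at any level, and naming genes from the neural against facial fit without the library labelled medial nasal prominence, which was also left out of the count of enriched genes. Transcript length and GC content came from GENCODE M21, matched by Ensembl identifier for 14786 genes (93.1%), and for 6903 never-tied genes (97.5%). That annotation belongs to a later build, so no coordinates are given.

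The methods were tested on simulated data built from the files. With 50 genes per fold and the floor applied, limma recovered 6%, 70%, 82% and 92% of genes at 2, 4, 8 and 16-fold for 3 libraries against 3 at E10.5 and E8.5, with 13 false calls among 10266 unchanged genes. For 3 against 4 libraries it recovered 0%, 42%, 70% and 90%, with 4 false calls among 9984. The floor shrinks large estimates, and a simulated log2 fold of 4 came out at a median of 2.91 in the neural stage comparison. In single-library counts, a simulated log2 shift of -1 was recovered as -0.99, 88% of genes at 2.83-fold and 100% at 4-fold or more were counted, and 2.03% of 1775 unchanged genes were counted. Of random lists, 12% lay outside the 5th to 95th percentile where 10% were due. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.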

Results

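RNA-seq profiles were made of the tissues that build the early mouse face, with 4 libraries at E8.5, 4 at E9.5 and 8 at E10.5. The E8.5 libraries were mesoderm, floor plate, non-floor plate neural epithelium and caudal brain neural epithelium. At E9.5 they were cranial mesenchyme, epidermal ectoderm, mandibular arch and maxillary arch. At E10.5 they were the lateral and medial nasal prominences, the mandibular and maxillary arches, the olfactory pit, and neural epithelium labelled lateral prominence, central and dorsal control. Each region and stage had 1 library, so differences between single libraries have no replicate error and no p-value. The values are ratios to the median of each gene over the 16 libraries. A level below is a multiple of the lowest value of the gene, and folds are relative to the median gene of the comparison. The labels state a read depth above 40000000, and no total per library was given.

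The gene lists separated the regions. The surface epithelium list had its highest mean log2 levels in E9.5 epidermal ectoderm (3.22) and E10.5 olfactory pit (3.20), against at most 0.78 in the other 14 libraries. The forebrain list was highest in E8.5 floor plate (3.92) and non-floor plate neural epithelium (3.55), and the midbrain and hindbrain list in E8.5 caudal brain (2.82). Neural crest genes had their highest mean in E8.5 mesoderm (3.34), and olfactory placode genes in the olfactory pit (4.39). Facial mesenchyme genes were highest in E9.5 cranial mesenchyme (2.81) and were between 1.72 and 2.54 in E8.5 mesoderm, epidermal ectoderm, the arches at both stages and the lateral nasal prominence. Erythroid genes, which mark blood, ranged from 0.02 in E8.5 non-floor plate neural epithelium to 4.78 in E9.5 cranial mesenchyme, and endothelium genes from 0.00 in the library labelled dorsal control to 2.89 in E8.5 mesoderm.

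**Figure D1:**
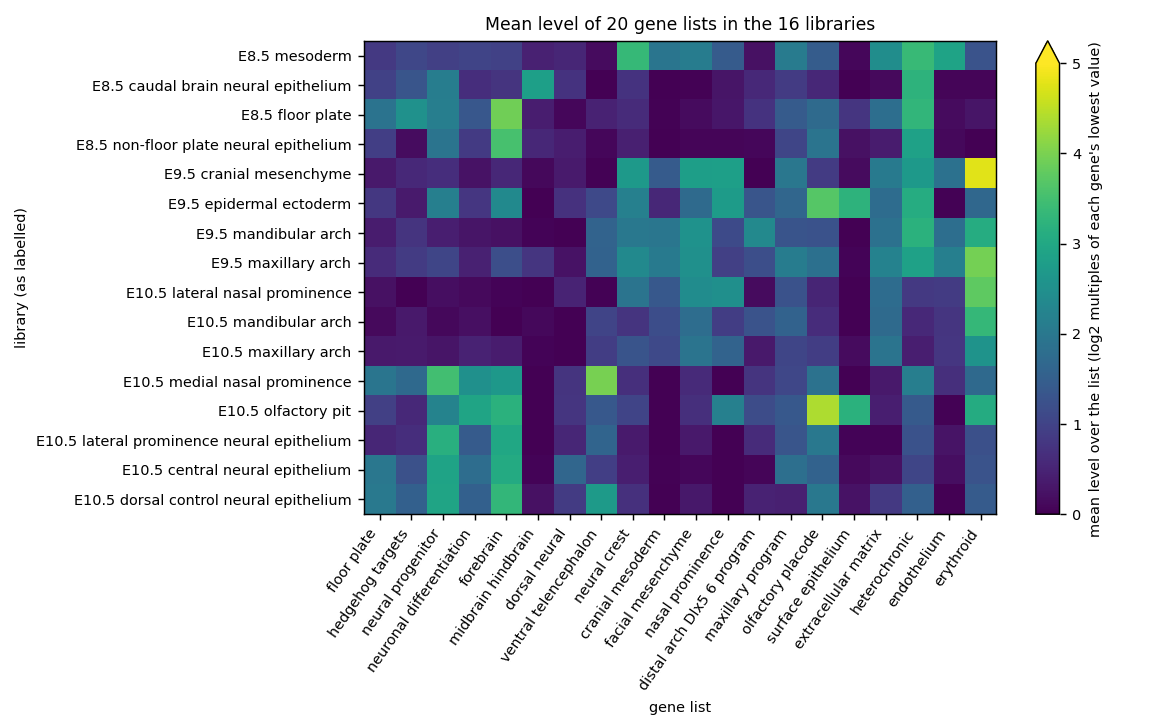
Mean log2 level over each of 20 fixed gene lists (columns) in each of the 16 libraries (colour, log2 multiples of the lowest value of each gene). Epidermal ectoderm and olfactory pit share surface epithelium genes (3.22 and 3.20), and the library labelled medial nasal prominence has neural progenitor genes at 3.49 and facial mesenchyme genes at 0.60.

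Across the atlas 101 genes were at least 4-fold above each other library, 1 to 16 per library with a median of 6, and 71 were so relative to the median gene. E8.5 caudal brain was marked by Hes3 (at least 16.2-fold over the next library), a Notch pathway repressor, and by Pax5 (at least 14.1-fold), En1 (10.8-fold) and Gbx2 (at least 7.37-fold), which act at the border of midbrain and hindbrain. E8.5 floor plate was marked by Pmp22 (9.62-fold), Nkx2-9 (9.05-fold), Hand1 (8.56-fold) and Foxa2 (at least 4.25-fold), E8.5 mesoderm by the neural crest gene Sox10 (at least 5.55-fold), and E8.5 non-floor plate neural epithelium by Aldh1a2 (6.96-fold), which makes retinoic acid. E9.5 cranial mesenchyme was marked by Prap1 (at least 70.8-fold), Guca2b (at least 16.5-fold) and S100g (at least 11.6-fold), and E9.5 maxillary arch by Hoxa2 (at least 8.13-fold), a patterning gene of the hindbrain crest. At E10.5 the lateral nasal prominence was marked by Cxcl13 (at least 10.8-fold), Hpgd (8.96-fold) and Pax7 (5.21-fold), and the olfactory pit by Nhlh1 (9.09-fold), Hes6 (4.83-fold), Runx1 (4.78-fold) and Pdgfa (4.27-fold). The library labelled central had Rspo3 (8.88-fold), Wnt8b (at least 7.66-fold) and Neurog2 (at least 4.37-fold), and the library labelled dorsal control had Zic4 (5.62-fold), Slit2 (5.28-fold) and Vax1 (4.16-fold). As deposited, Pax7 (3.16-fold), Pdgfa (3.91-fold) and Vax1 (3.31-fold) were under 4-fold. The E10.5 mandibular and maxillary libraries were marked by gene segments of antigen receptors, Ighj1 (at least 26.1-fold) and Traj17 (at least 15.04-fold), and the maxillary library also by Fos (5.17-fold), an immediate early gene. The library labelled medial nasal prominence had Islr2 (at least 5.28-fold).

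Of the 8 libraries of E10.5, 6 had lower values than the rest. The median never-tied gene, in log2 relative to its mean over libraries, lay at -0.82 in the maxillary arch, -0.70 in the mandibular arch, -0.38 in the lateral nasal prominence, and -0.28, -0.19 and -0.07 in the central, lateral prominence and dorsal control neural epithelium. In these 6 libraries 63.9% to 81.5% of the genes of known level sat at the floor, against 50.7% to 59.1% in the other 10. The 61 histone genes had a median level of 1 in the E10.5 mandibular and 1.39 in the E10.5 maxillary arch, against 19.3 and 13.3 at E9.5 and 21.6 in the library labelled medial nasal prominence. Some genes were all or none across libraries. Tardbp, an RNA-binding protein gene, was under 2 times its lowest value in 8 libraries and at 20 times or more in the other 8, and Tpr, Lars2 and Ttc3 also had 0 libraries in between. These 4 genes recur among the largest differences below.

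**Figure D2:**
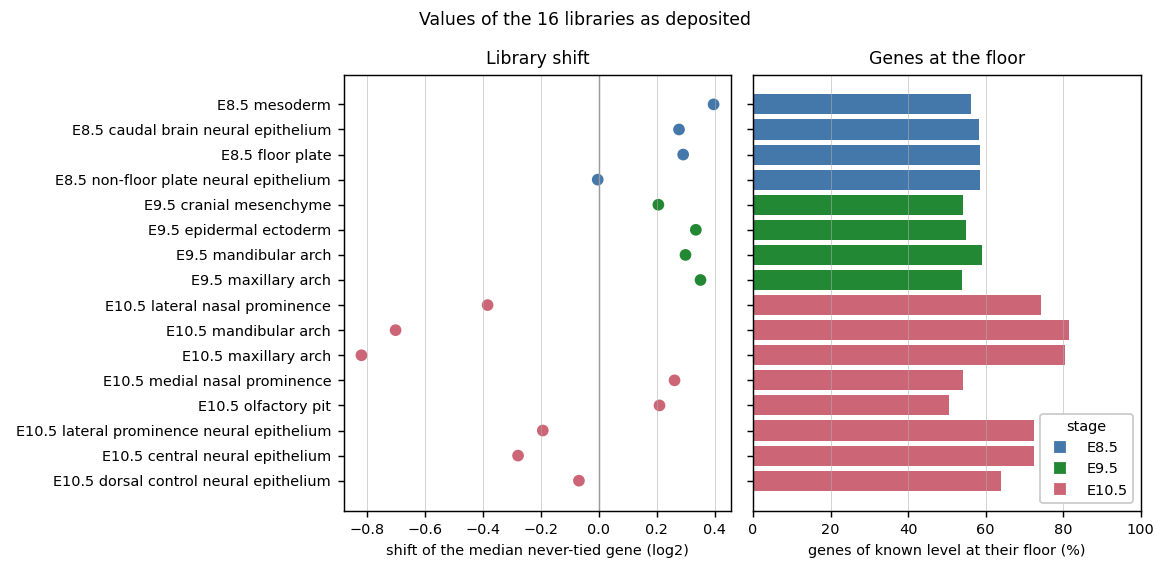
Shift of the median never-tied gene (dots, log2, left) and share of genes of known level at their floor (bars, percent, right) for each of the 16 libraries, coloured by stage. The E10.5 maxillary arch has the lowest shift (-0.82) and the E10.5 mandibular arch the largest share at the floor (81.5%).

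At E8.5 the floor plate was compared with non-floor plate neural epithelium, to ask which genes mark the ventral midline. Hedgehog pathway genes stood out. Nkx2-9, a homeobox gene of the ventral neural tube, was at least 87.8-fold higher, Ptch1, the hedgehog receptor, 9.88-fold higher, and Gli1, the pathway effector, at least 5.91-fold higher. Of 8 measured hedgehog targets 3 were higher and 0 lower, with a median log2 ratio of 2.24 (percentile 100 of random lists). Of 9 floor plate genes 3 were higher and 0 lower, namely Foxa2 (at least 7.46-fold), Shh (at least 5.17-fold) and Spon1 (2.36-fold), with a median of 0.87 (percentile 100). Keratins of surface epithelium were also higher, with Krt19 (at least 7.06-fold), Krt8 (at least 5.28-fold) and Krt18 (4.22-fold) as 3 of 14 genes and 0 lower. Among the largest differences were Hand1 (at least 40.2-fold), Postn (at least 26.4-fold), Pmp22 (24.9-fold), S100a11 (22.8-fold), Acta2 (at least 17.2-fold), Bmp4 (at least 13.1-fold) and Col1a1 (at least 12.7-fold), genes of mesenchyme, muscle actin and signalling, and Tardbp (at least 47.8-fold). Whether the keratin, mesenchyme and muscle actin genes belong to floor plate cells or to other tissue in this single library was not tested. Of 15 secreted ligands, 2 were higher (Shh and Bmp4) and 0 lower.

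Dorsal neural genes were lower in the floor plate library for 2 of 13 members, with Emx2 at 7.14-fold and 0 higher. Of 12 neural crest genes, 1 was higher (Snai2, 8.22-fold) and 1 lower (Crabp1, 2.02-fold, not lower as deposited). Among the largest lower values were those of Ttc3 (at least 138-fold) and of ribosomal and other pseudogenes such as Rps15a-ps7 (33.3-fold) and Oaz1-ps (at least 32.4-fold), whose reads can be shared with their parent genes. Relative to the median gene no member was counted in either direction in the lists of neural progenitor (0 of 10, 1 higher as deposited), cranial mesoderm (0 of 12), endothelium (0 of 11), erythroid (0 of 12), muscle and heart (0 of 6), proliferation (0 of 10), sex-linked (0 of 5, 1 higher as deposited), stress (0 of 8), sensory ganglion (0 of 3), macrophage (0 of 1) and notochord genes (0 of 1). In all, 893 of 2341 eligible genes differed, with 379 higher and 514 lower as deposited (42.4% higher). The libraries differed by a log2 shift of 0.30, and relative to the median gene 258 were higher and 605 lower (29.9% higher).

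Caudal brain neural epithelium at E8.5 was compared with the same non-floor plate library, to separate posterior from anterior neural identity. Midbrain and hindbrain genes were higher for 4 of 9 members and lower for 0 (median log2 ratio 3.73, percentile 100). They were Pax5 (at least 24.9-fold), En1 (at least 21.4-fold), Pax8 (13.5-fold) and Gbx2 (at least 13.1-fold), and Hes3 (at least 28.6-fold) was the highest of the named genes. Forebrain genes were lower for 8 of 10 members (7 as deposited) and higher for 0 (median -3.07, percentile 0). Lhx2 (at least 71.9-fold) and Six3 (at least 60.4-fold), which pattern the forebrain and eye, were lowest, and Hesx1 (at least 11.8-fold), Rax (at least 8.88-fold), Otx2 (4.27-fold) and Otx1 (2.33-fold) were lower too. Secreted ligands of the isthmus, the signalling centre between midbrain and hindbrain, were higher for 4 of 15 members and lower for 0, with Fgf18 (at least 13.3-fold), Wnt1 (at least 13.2-fold), Fgf17 (at least 4.82-fold) and Fgf15 (2.59-fold).

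Other differences included Sparc (at least 22.2-fold), Igdcc3 (20.6-fold) and Lsmd1 (at least 15.1-fold) higher, and Pax6 (at least 52.1-fold), Six3os1 (at least 39.5-fold), Shisa2 (at least 29.6-fold), Eras (26.3-fold), Fzd5 (at least 20.02-fold), Fezf1 (at least 19.0-fold) and Aldh1a2 (at least 15.6-fold) lower. Neural progenitor genes split, with Fabp7 (at least 6.997-fold) and Sox21 (2.87-fold) higher, Pax6 lower and 7 of 10 neither. Dorsal neural genes had Wnt1 higher, Emx2 lower (at least 7.94-fold) and 11 of 13 neither. Crabp1 (6.24-fold), which binds retinoic acid, was the 1 higher of 12 neural crest genes. Counts were 0 higher and 0 lower for cranial mesoderm, endothelium, erythroid, muscle and heart (1 higher as deposited), stress, sensory ganglion, sex-linked, proliferation, macrophage and notochord genes. As deposited, 705 of 2187 eligible genes differed, 253 higher and 452 lower (35.9% higher). After the log2 shift of 0.27 the split was 179 and 542 (24.8% higher).

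E8.5 mesoderm carried mesenchyme, neural crest, vessel and blood genes when compared with non-floor plate neural epithelium. Neural crest genes were higher for 10 of 12 members and lower for 0 (median log2 ratio 2.71, percentile 100), among them Ets1 (at least 11.8-fold), Sox10 (at least 9.70-fold), Crabp1 (9.63-fold) and Snai2 (8.06-fold). Cranial mesoderm genes were higher for 6 of 12 and lower for 0 (median 2.54, percentile 100), with Twist1 (at least 15.8-fold), Foxc1 (at least 11.4-fold) and Foxc2 (at least 7.02-fold). Endothelium genes were higher for 7 of 11 and lower for 0 (median 2.41, percentile 100), with Cdh5 (at least 12.0-fold), Kdr (at least 9.31-fold) and Egfl7 (8.64-fold). The embryonic globins Hba-x (at least 27.7-fold), Hbb-bh1 (at least 25.5-fold) and Hbb-y (at least 5.99-fold) were the 3 higher of 12 erythroid genes, with 0 lower.

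Matrix genes were higher in E8.5 mesoderm for 4 of 11 members (5 as deposited) and lower for 0, with Lum (at least 16.3-fold), Col3a1 (at least 8.66-fold), Col1a2 (8.05-fold) and Col5a1 (3.55-fold). Sparc (at least 45.8-fold), Hapln1 (at least 32.0-fold), Igf2 (26.8-fold), Rspo1 (at least 19.9-fold) and Plxnd1 (at least 18.2-fold) were among the largest, as was the all-or-none gene Tardbp (at least 50.8-fold). Forebrain genes were lower for 8 of 10 members (median -3.21, percentile 0), with Six3 at 26.0-fold, and neural progenitor genes for 4 of 10 (3 as deposited), with Pax6 at 24.9-fold, Sox21 at 7.08-fold, Sox2 at 6.89-fold and Cdh2 at 2.30-fold. Lars2 was at least 374-fold lower. Of the sex-linked genes Eif2s3y was the 1 lower of 5 (0 as deposited), and surface epithelium, muscle and heart, stress, proliferation, macrophage and notochord genes had 0 members counted in either direction. Of 2761 eligible genes 1165 differed, 651 higher and 514 lower as deposited (55.9% higher), and relative to the median gene, with a log2 shift of 0.41, 402 and 583 (40.8% higher).

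**Figure D3:**
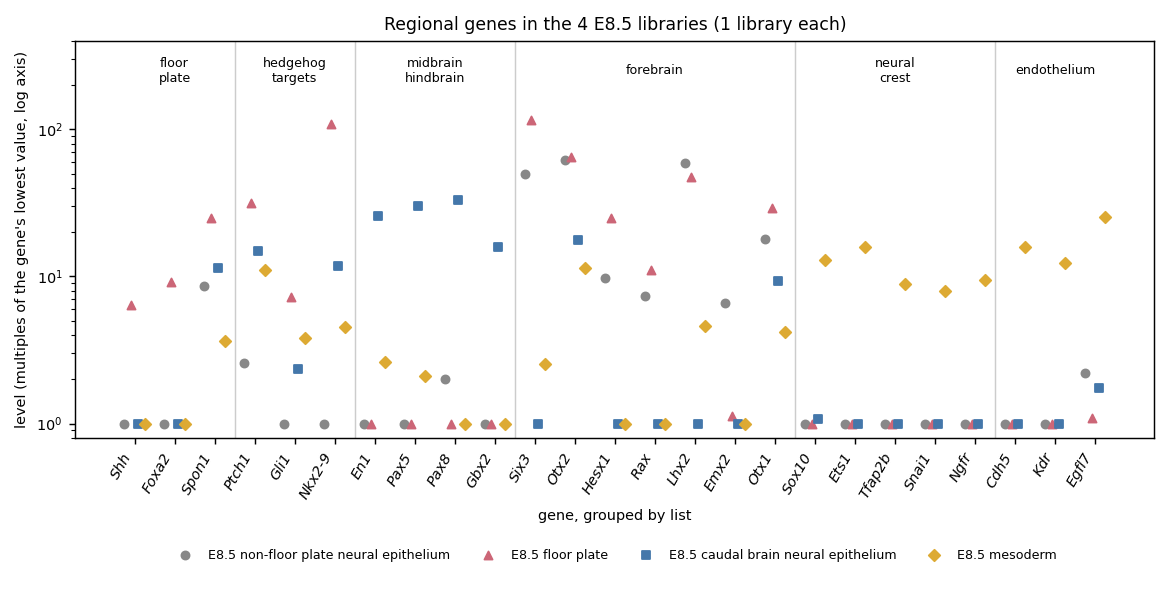
Level (log axis, multiples of the lowest value of each gene) of regional genes in the 4 libraries of E8.5, grouped by list, 1 library per symbol. Nkx2-9 reaches 108 in the floor plate, Pax5 reaches 30.2 in caudal brain, Six3 is at 1 in caudal brain and 116 in the floor plate, and Sox10 reaches 12.9 in mesoderm.

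The mandibular and maxillary arches of E9.5 were compared to ask which genes separate the lower from the upper jaw. Distal arch genes were higher in the mandibular library for 4 of 12 members and lower for 0 (median log2 ratio 1.08, percentile 100). They were Hand2 (at least 25.7-fold) and Hand1 (at least 5.93-fold), which pattern the distal arch, and Dlx6 (3.35-fold) and Dlx5 (2.16-fold). Maxillary program genes were lower for 2 of 8 members, Pou3f3 (at least 8.34-fold) and Nr2f1 (3.56-fold), and higher for 0 (median -0.52, percentile 0.7). Msx2 (10.1-fold) and Msx1 (3.62-fold), targets of BMP signalling, and Prrx2 (2.08-fold) were higher among 15 facial mesenchyme genes, and Twist2 was lower (4.07-fold). Wnt5a (2.90-fold) was the 1 higher of 15 secreted ligands.

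Cranial mesoderm genes of the E9.5 arches went both ways, with Foxf1 (at least 6.63-fold) and Tcf21 (2.75-fold) higher in the mandibular library and Twist2 and Foxc1 (2.94-fold) lower among 12 members. Of the largest differences, Fstl1 (at least 31.9-fold), Gpr50 (at least 16.7-fold), Dlk1 (12.6-fold) and the all-or-none gene Tpr (at least 94.1-fold) were higher, and Foxp2 (at least 20.1-fold), Hoxa2 (at least 18.0-fold), Pf4 (at least 14.2-fold), a platelet gene, and Ndufa2 (13.7-fold) lower. Forebrain genes had a mean log2 level of 1.195 in the maxillary library and 0.22 in the mandibular one, with Lhx2 at levels of 13.1 and 4.68. A share of other tissue in the maxillary library, for Hoxa2 or these genes, was not tested. Blood genes were lower in the mandibular library for 4 of 12 members, Hbb-b2 (10.1-fold), Hbb-y (4.65-fold), Hbb-bh1 (4.53-fold) and Hba-a1 (2.62-fold), with 0 higher. The stress list had Jun (3.18-fold) and Dnajb1 (2.22-fold) lower among 8, neural crest had Tfap2a lower (2.22-fold) among 12, and Xist was 3.22-fold lower among 5 sex-linked genes. Muscle and heart genes had a median of 1.03 (percentile 100) with 0 of 6 counted, and surface epithelium, endothelium, proliferation, sensory ganglion, macrophage and notochord genes had 0 counted in either direction. As deposited, 570 of 2477 eligible genes differed, 183 higher and 387 lower, and relative to the median gene (log2 shift -0.03) 192 and 370.

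At E10.5 the same comparison again gave distal arch genes higher in the mandibular library, for 3 of 12 members with 0 lower (median log2 ratio 1.58, percentile 99.6). They were Hand2 (at least 15.2-fold), Pitx1 (at least 4.93-fold), a gene of mandible and hindlimb, and Dlx5 (4.14-fold). The nuclear receptors Nr2f1 (5.91-fold) and Nr2f2 (4.01-fold) were the 2 higher in the mandibular library of the 8 members of the maxillary program. Facial mesenchyme genes were lower for 3 of 15, Alx1 (5.95-fold), Six2 (3.92-fold) and Alx4 (2.48-fold), with 0 higher. Vcan (at least 76.8-fold), which encodes a matrix proteoglycan, Usp9x (32.4-fold), Gpr50 (at least 28.9-fold), Ighj1 (at least 27.7-fold), Pbrm1 (26.0-fold) and Tardbp (at least 38.4-fold) were higher. Prr14l (16.8-fold), Pdrg1 (8.30-fold), Igf1 (6.83-fold), Pdgfa (at least 5.77-fold) and Gata3 (at least 5.25-fold) were lower.

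Immediate early genes of the E10.5 arches were lower in the mandibular library for 3 of 8 stress list members, Fos (4.87-fold), Jun (4.57-fold) and Egr1 (3.84-fold), with 0 higher (median -1.94, percentile 0). Globins were higher for 4 of 12 erythroid genes, with Hbb-bh1 (5.51-fold), Hbb-b2 (3.92-fold), Hbb-y (3.01-fold) and Hba-a1 (2.80-fold). Crabp1 (3.46-fold) was lower among 12 neural crest genes, and 0 members were counted for cranial mesoderm, surface epithelium, secreted ligands, endothelium, muscle and heart, proliferation, sex-linked, macrophage and notochord genes. Of 576 eligible genes 381 differed, 230 higher and 151 lower as deposited, and relative to the median gene (log2 shift 0.03) 228 and 156. Usp9x, Pbrm1 and Rnf44 (16.5-fold) lay in the maxillary library at least 16.9-fold below the next lowest of the 16 libraries.

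Only 377 genes were eligible in the arch comparisons of both stages. Of these, 15 were higher in the mandibular library at both, where chance gives 15.3, 5 were lower at both (16.8 by chance), and 113 went in opposite directions (67.2 by chance). Relative to the median gene the counts were 15, 4 and 109. The shared higher genes included Hand2 (at least 25.7-fold at E9.5 and 15.2-fold at E10.5), Fstl1 (at least 31.9 and 11.5), Gpr50 (at least 16.7 and 28.9), Unc5c (4.75 and 3.91), Cited1 (2.88 and 10.51), Dlk1 (12.6 and 2.06), Dlx5 (2.16 and 4.14), and the imprinted genes Igf2 (2.23 and 10.1) and H19 (2.12 and 5.05). Those lower at both were Postn (5.20 and 4.57), Igf1 (3.22 and 6.83), Jun (3.18 and 4.57) and Zfp579 (2.44 and 3.10). Hand2, Fstl1 and Gpr50 were at their floor in both maxillary libraries. The opposite group held the globins Hbb-bh1, Hbb-b2, Hbb-y and Hba-a1 and the maxillary program gene Nr2f1.

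**Figure D4:**
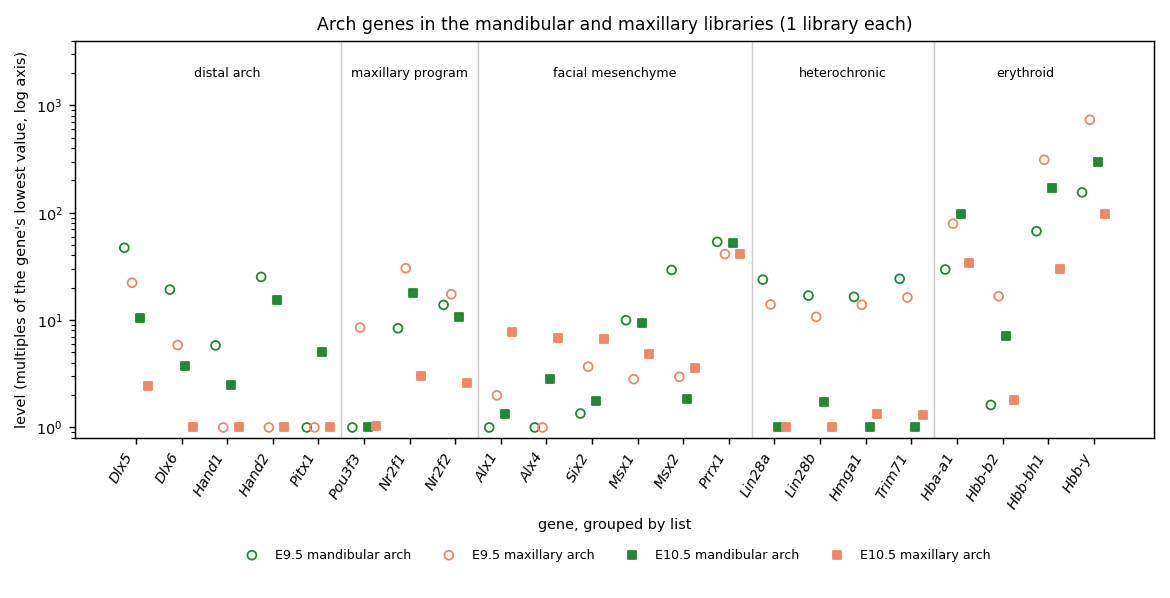
Level (log axis, multiples of the lowest value of each gene) of arch genes in the mandibular and maxillary libraries of E9.5 (open circles) and E10.5 (filled squares), 1 library each. Hand2 is at 1 in both maxillary libraries and at 25.2 and 15.5 in the mandibular ones, and Lin28a is at 1 in both E10.5 libraries.

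The mandibular arch was then followed from E9.5 to E10.5. The heterochronic genes, which time early development through the let-7 pathway, were lower at E10.5 for 5 of 7 members (median log2 ratio -2.29, percentile 0.08). Trim71 was at least 12.2-fold lower, Lin28a at least 12.0-fold, Hmga1 8.31-fold and Lin28b 4.90-fold, and Hmga2 was 4.11-fold higher. Matrix genes were higher for 2 of 11, Col3a1 (4.72-fold) and Col1a1 (4.65-fold), with 0 lower (1 as deposited), and Col2a1, the cartilage collagen, was 3.04-fold higher as the 1 of 6 chondrogenic genes, where 0 were higher and 2 lower as deposited. Among 15 facial mesenchyme genes 3 were lower (4 as deposited), Dlx2 (8.59-fold), Msx2 (8.09-fold) and Prrx2 (2.61-fold). Neural crest genes were lower for 3 of 12 (4 as deposited), Crabp1 (6.32-fold), Ets1 (5.84-fold) and Snai1 (5.10-fold), and Snai2 was 2.43-fold higher relative to the median gene and not higher as deposited. Cranial mesoderm had Tcf21 (at least 3.41-fold) and Foxf1 (at least 3.28-fold) lower among 12, and endothelium had Flt1 (at least 2.60-fold) and Kdr (2.08-fold) lower among 11, 5 as deposited.

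Among the highest ratios of E10.5 over E9.5 in the mandibular arch were those of Vcan (at least 156-fold), Ighj1 (at least 56.2-fold), Lars2 (at least 43.0-fold), Ndufa6 (42.2-fold), Brwd1 (at least 37.0-fold), Bcl11a (at least 29.99-fold) and Foxp2 (at least 22.7-fold). Among the lowest were those of Rmrp (88.2-fold), the RNA of an RNase complex, and the histone genes Hist2h3c2 (82.0-fold), Hist1h2bm (75.7-fold), Hist2h3b (62.5-fold) and Hist1h2bb (35.8-fold). Globins were higher for 4 of 12 erythroid genes (3 as deposited), with Hbb-b2 at 8.77-fold, Hba-a1 at 6.50-fold, Hbb-bh1 at 4.997-fold and Hbb-y at 3.80-fold, and Slc4a1 was 2.05-fold lower. Egr1 was at least 10.2-fold higher as the 1 of 8 stress genes, Xist was 8.79-fold higher, and Uty (at least 4.27-fold) and Eif2s3y (3.09-fold) on the Y chromosome were lower. Cdc20 (3.32-fold) was the 1 lower of 10 proliferation genes (2 as deposited), and muscle and heart, surface epithelium, sensory ganglion, macrophage and notochord genes had 0 counted. Of 1975 eligible genes, 169 were higher and 1486 lower as deposited (10.2% higher). The log2 shift between the libraries was -0.99, and relative to the median gene 278 were higher and 1035 lower (21.2% higher).

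In the maxillary arch the heterochronic genes were lower at E10.5 for the same count of 5 of 7 members, with 0 higher (median -2.20, percentile 0.165). Lin28a was at least 6.26-fold lower, Trim71 5.53-fold, Lin28b 4.79-fold, Hmga1 4.61-fold and Igf2bp1 2.62-fold. Of 15 facial mesenchyme genes 5 were higher relative to the median gene, with Alx4 (at least 15.4-fold), Alx1 (8.72-fold), Six2 (4.07-fold), Prrx1 (2.25-fold) and Twist1 (2.03-fold), and lower for Dlx2 (6.72-fold) and Twist2 (at least 2.31-fold). As deposited 2 were higher and 6 lower, and the ratios of Prrx1 and Twist1 were 0.01 and -0.14 in log2. Prrx1 and Twist1 are likewise the 2 higher of 12 cranial mesoderm genes relative to the median gene, with Twist2 lower, where 0 were higher and 3 lower as deposited. Matrix genes were higher for 3 of 11, Col1a2 (5.64-fold), Col1a1 (5.44-fold) and Postn (4.601-fold), with 0 lower (1 as deposited), and the chondrogenic list had Runx2 (15.1-fold), which drives bone formation, and Sox5 (2.32-fold) higher and Col9a1 (3.43-fold) lower among 6, against 1 higher and 2 lower as deposited. Snai2 (2.13-fold) was higher and Ets1 (3.02-fold) and Crabp1 (2.19-fold) lower among 12 neural crest genes, with 0 higher and 5 lower as deposited, where the log2 ratio of Snai2 was -0.07.

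Immediate early genes were higher in the E10.5 maxillary arch, with Egr1 (26.1-fold), Fos (at least 22.3-fold) and Jun (2.61-fold) higher and Dnajb1 (4.93-fold) lower among 8 stress genes (median 2.18, percentile 100), with 2 higher as deposited. Mitochondrial transcripts were among the largest differences, with mt-Nd2 (39.3-fold), mt-Te (37.7-fold) and mt-Nd6 (33.7-fold) higher, as were Tpr (at least 416-fold), Lars2 (at least 113-fold), Slitrk6 (43.2-fold), Brwd1 (at least 38.1-fold) and Traj17 (at least 31.0-fold). Tardbp (at least 29.7-fold), Rnf44 (22.5-fold), Uqcrq (19.5-fold), Hist2h3c2 (17.8-fold), Hist1h2bm (16.9-fold) and Rmrp (15.5-fold) were lower. Erythroid genes were lower for 3 of 12, the globins Hbb-bh1 (4.63-fold), Hbb-b2 (4.17-fold) and Hbb-y (3.41-fold), and for 6 as deposited. Kdr (2.38-fold) was lower among 11 endothelium genes (4 as deposited), Xist was 5.24-fold higher, and Eif2s3y (at least 6.44-fold) and Uty (at least 2.86-fold) were lower. Surface epithelium, muscle and heart, proliferation (1 lower as deposited), macrophage and notochord genes had 0 counted in either direction. Of 2140 eligible genes 159 were higher and 1778 lower as deposited (8.21% higher), for a log2 shift of -1.16, and relative to the median gene 230 and 1360 (14.5% higher). With the GC trend removed the total was 1262 in place of 1937.

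Both arches shared many stage differences. Among 1439 genes eligible in both, 39 were higher at E10.5 in both (4.86 by chance), 961 lower in both (875.3 by chance) and 72 opposite (146.4 by chance). Relative to the median gene these were 72 (17.1 by chance), 520 (460.2) and 115 (198.9), and with the GC trend removed 452 were shared in all.

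Epidermal ectoderm of E9.5 was compared with cranial mesenchyme, which separates the covering layer from the tissue beneath it. Surface epithelium genes were higher in the ectoderm for 9 of 14 members with 0 lower (median log2 ratio 2.86, percentile 100). Cldn6, a tight junction gene, was at least 75.1-fold higher, Esrp1, an epithelial splicing factor, at least 25.0-fold, Krt18 19.4-fold, Grhl2 at least 17.5-fold, Epcam 17.4-fold and Cdh1 at least 9.12-fold. Facial mesenchyme genes were lower for 8 of 15, among them Alx1 (at least 12.6-fold), Pdgfra (8.11-fold), Pdgfrb (5.61-fold) and Twist1 (4.02-fold), and Msx2 was at least 8.08-fold higher. Cranial mesoderm genes were lower for 4 of 12, Pdgfra, Foxc1 (4.95-fold), Twist1 and Prrx1 (3.64-fold), and neural crest genes for 5 of 12 (4 as deposited), with Ets1 (at least 10.3-fold), Crabp1 (4.64-fold), Sox9 (4.12-fold), Snai1 (3.23-fold) and Ngfr (2.16-fold), with 0 higher in either list. Bmp4 (at least 5.49-fold) and Bmp2 (at least 4.63-fold) were the 2 higher of 15 secreted ligands.

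Vessel and blood genes were lower in the ectoderm library. Endothelium genes were lower for 4 of 11, Egfl7 (at least 12.1-fold), Emcn (10.7-fold), Cdh5 (at least 10.6-fold) and Kdr (at least 6.77-fold), and erythroid genes for 9 of 12, with Hbb-bh1 at 133.7-fold, Hbb-y at 62.9-fold and Hba-a1 at 25.4-fold. Matrix genes were split, with Postn (at least 11.6-fold) and Col1a1 (3.08-fold) higher and Col1a2 (6.46-fold), Col3a1 (5.13-fold) and Fbn2 (2.27-fold) lower among 11. Dlx5 (at least 56.6-fold), Igfbp5 (39.7-fold), Eya2 (at least 38.0-fold), Slc2a3 (30.6-fold), Otx1 (at least 28.5-fold), Dsp (at least 24.8-fold) and Igfbp2 (23.9-fold) were higher, and Prap1 (at least 162.9-fold) and the all-or-none genes Lars2, Ttc3 and Tpr (at least 186, 77.4 and 71.5-fold) lower. Xist was 5.82-fold higher, and Eif2s3y (6.53-fold) and Uty (5.90-fold) lower. Stress, proliferation, muscle and heart, macrophage and notochord genes had 0 counted. As deposited, 1418 of 2886 eligible genes differed, 561 higher and 857 lower (39.6% higher), with a log2 shift of 0.18, and relative to the median gene 469 and 932 (33.5% higher).

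The lateral nasal prominence and the library labelled medial nasal prominence, which in the embryo flank the nasal pit, were compared at E10.5. Nasal prominence genes were higher in the lateral library for 7 of 10 members with 0 lower (median log2 ratio 3.69, percentile 100), with Alx1 (at least 42.6-fold), Msx1 (at least 32.9-fold), Pax7 (at least 22.7-fold) and Alx4 (at least 15.5-fold). Facial mesenchyme genes were higher for 9 of 15, with Prrx1 (at least 42.0-fold), Twist1 (at least 40.1-fold) and Tfap2b (at least 23.4-fold), and Dlx1 (at least 14.4-fold) and Dlx2 (at least 13.5-fold) were lower. Olfactory placode genes were lower for 6 of 16 and higher for 2, with Eya1 at least 10.7-fold higher, and Lhx2 (at least 20.6-fold) and Sox2 (at least 16.6-fold), lower here, are also genes of the forebrain and its progenitors. Matrix genes were higher for 4 of 11 with 0 lower, with Col1a2 (at least 72.7-fold) and Col3a1 (at least 28.0-fold).

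The library labelled medial nasal prominence thus had brain genes and few of the face. In it Nkx2-1 was at a level of 49.9, Olig2 at 28.2, Dlx6 at 27.3 and Shh at 11.7, which mark ventral forebrain, while Prrx1, Twist1, Alx1, Alx4 and Msx1 were at 1. Its nearest library by Spearman correlation across genes was the one labelled dorsal control neural epithelium (0.331), and genes are not independent replicates. Lateral over medial, Tpr (at least 178.9-fold), Igf1 (at least 178.1-fold), Ttc3 (at least 99.7-fold), Crabp1 (96.2-fold), Tardbp (at least 66.4-fold) and Hba-a1 (40.4-fold) were higher, and Ckb (at least 119.6-fold), Meis2 (40.4-fold), Gpr50 (at least 37.2-fold), Fabp7 (at least 35.9-fold), Ddah1 (34.6-fold), Hist2h3c2 (34.5-fold), Otx2 (at least 33.3-fold) and Dpysl5 (at least 32.9-fold) lower. Erythroid genes were higher for 7 of 12 and Emcn (3.73-fold) for endothelium, 1 of 11, with 0 lower in both lists. Col2a1 (4.19-fold) was higher and Sox6 (at least 5.04-fold) and Sox9 (3.95-fold) lower (3 as deposited) among 6 chondrogenic genes, Wnt5a (7.52-fold) was higher and Shh (at least 7.41-fold) and Fgf15 (at least 3.35-fold) lower among 15 ligands, and Xist was 2.53-fold lower among 5. Of the sensory ganglion genes Isl1 (at least 3.94-fold) was lower, and surface epithelium, stress and proliferation (1 lower in each of these 2 as deposited), muscle and heart, macrophage and notochord genes had 0 counted relative to the median gene. As deposited, 1686 of 1999 eligible genes differed, 287 higher and 1399 lower (17.02% higher), with a log2 shift of -0.65, and relative to the median gene 377 and 1068 (26.1% higher).

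The olfactory pit, the ingrowing placode that gives rise to the nasal lining, was compared with the lateral nasal prominence beside it. Olfactory placode genes were higher in the pit for 15 of 16 members with 0 lower (median log2 ratio 3.25, percentile 100), among them Lhx2 (at least 37.8-fold), Dlx5 (at least 32.4-fold), Six3 (at least 24.05-fold), Sox2 (at least 18.6-fold) and Pax6 (at least 17.8-fold). Neuronal genes were higher for 7 of 12 with 0 lower, with Elavl4 (at least 29.6-fold), Tubb3 (at least 18.1-fold), Nhlh1 (at least 16.8-fold), Stmn2 (at least 11.2-fold) and Neurod1 (at least 7.72-fold). Surface epithelium genes were higher for 9 of 14 with 0 lower, with Cldn6 (at least 96.4-fold), Epcam (at least 42.4-fold) and Krt18 (at least 15.3-fold). Mesenchyme genes of the face were lower for 8 of 15, with Twist1 (at least 38.7-fold), Prrx1 (38.1-fold) and Alx1 (35.4-fold), and Six2 was 4.13-fold higher (median -3.72, percentile 0).

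Growth factor genes of the pit included Pdgfa (at least 58.3-fold higher), Dlk1 (at least 53.2-fold), Fgf9 (at least 5.10-fold) and Bmp4 (2.19-fold), the last 2 being the higher of 15 ligands with 0 lower, and Igfbp2 was 29.3-fold higher. Igf1 (88.7-fold), Col1a2 (45.5-fold), Hpgd (at least 33.2-fold), Cped1 (at least 32.4-fold), Tpr (at least 172.4-fold) and Tardbp (at least 64.0-fold) were lower, and Cops2 (42.8-fold) lay in the pit 25.8-fold below the next lowest of the 16 libraries. Emcn (at least 7.61-fold) was lower among 11 endothelium genes, and 5 of 12 erythroid genes were lower relative to the median gene and 3 as deposited. Isl1 (at least 5.28-fold) was higher among sensory ganglion genes, among 8 stress genes Jun (2.56-fold) was lower relative to the median gene and 1 was higher and 0 lower as deposited, and Xist was 12.5-fold lower, at its lowest value in the pit, with 1 sex-linked gene higher as deposited. Proliferation, muscle and heart, macrophage and notochord genes had 0 counted. As deposited, 1378 of 1914 eligible genes differed, 1238 higher and 140 lower (89.8% higher), with a log2 shift of 0.60, and relative to the median gene 875 and 196 (81.7% higher).

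Neural epithelium of E10.5 was compared between its lateral prominence and the library labelled dorsal control. Ventral telencephalon genes were lower in the lateral prominence library for 4 of 13 members with 0 higher, namely Nkx2-1 (48.1-fold), Shh (at least 11.7-fold), Isl1 (5.06-fold) and Olig2 (4.03-fold). Forebrain genes split 3 and 3 among 10, with Emx2 (at least 11.8-fold), Otx1 (9.53-fold) and Lhx2 (2.39-fold) higher and Nkx2-1, Six3 (4.07-fold) and Otx2 (3.73-fold) lower. Secreted ligands were lower for 3 of 15, Fgf18 (at least 13.0-fold), Shh and Fgf15 (3.99-fold), with 0 higher (median log2 ratio -2.09, percentile 0). Dorsal neural genes had Emx2 higher and Zic1 (15.8-fold) lower among 13. Pax6 (at least 46.5-fold), which marks dorsal forebrain progenitors, Cnot3 (29.6-fold), Pcdh19 (20.2-fold), Acvr2a (16.7-fold), Id4 (15.7-fold), Epha3 (at least 14.7-fold), Robo2 (13.5-fold) and Nr2f1 (at least 13.1-fold) were higher. Ttc3 (at least 132.4-fold), Sulf1 (38.2-fold), Slit2 (24.6-fold), Fstl1 (at least 21.2-fold), Gpr50 (at least 21.01-fold), Rspo1 (at least 20.2-fold) and Lrp2 (at least 19.2-fold) were lower.

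Neural progenitor genes of this comparison had Pax6 and Sox3 (at least 6.17-fold) higher and Hes5 (7.05-fold) lower among 10, and neuronal, midbrain and hindbrain, endothelium, muscle and heart, stress, sex-linked, proliferation, macrophage and notochord genes had 0 counted. Hba-x (2.06-fold) was the 1 lower of 12 erythroid genes and Isl1 the 1 lower of 3 sensory ganglion genes. Of 1178 eligible genes 655 differed, 161 higher and 494 lower as deposited (24.6% higher), and relative to the median gene (log2 shift -0.09) 170 and 465. Against the library labelled central in its place, 262 genes differed. Cnot3 and Orc4 (19.2-fold higher) lay in the library labelled dorsal control at least 12.1-fold below the next lowest of the 16 libraries.

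The library labelled central neural epithelium had dorsal genes where the one labelled dorsal control had ventral genes. Dorsal neural genes were higher in it for 4 of 13 members, Emx2 (at least 16.4-fold), Wnt8b (at least 12.7-fold), Neurog2 (at least 7.23-fold) and Wnt7b (at least 6.54-fold), and lower for Zic1 (3.76-fold), with a median log2 ratio of 1.57 (percentile 100). Ventral telencephalon genes were lower for 6 of 13 with 0 higher (median -1.64, percentile 0), with Nkx2-1 (22.7-fold), Dlx6 (at least 8.03-fold), Isl1 (at least 6.14-fold), Dlx5 (at least 5.41-fold), Dlx1 (3.84-fold) and Olig2 (3.05-fold). In levels, the library labelled dorsal control had Nkx2-1 at 101.2 and Shh at 12.4. The library labelled central had these at 3.91 and 7.04, and Shh was not counted as different. It had Pax6 at 66.6, Otx1 at 29.0, Fezf2 at 27.1 and Emx2 at 14.4, against 1, 1.37, 4.67 and 1 in the one labelled dorsal control. The abbreviations of these 2 libraries in the file names are also crossed against their labels.

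Pax6 (at least 75.8-fold), Nr2f2 (42.6-fold), Rspo3 (at least 31.0-fold), Otx1 (24.1-fold), Nr2f1 (at least 23.6-fold), Acvr2a (22.2-fold) and Brwd1 (at least 37.9-fold) were among the highest in the library labelled central, and Tpr (at least 157.4-fold), Gpr50 (14.2-fold), Ucp2 (14.0-fold), Mbip (12.8-fold), Fgf18 (at least 12.1-fold) and Vax1 (at least 10.9-fold) among the lowest. Forebrain genes were higher for 3 of 10, Otx1, Emx2 and Fezf2 (6.60-fold), and lower for 4, among them Nkx2-1, Six3 (8.87-fold) and Otx2 (2.07-fold). Neuronal genes had Elavl4 (4.11-fold) and Nefm (2.34-fold) higher and Tubb3 (2.31-fold) lower among 12, with 2 lower as deposited (median 0.74, percentile 100). Neural progenitor genes had Pax6 higher and Hes5 (7.21-fold) lower among 10 (3 lower as deposited), and ligands had Wnt8b and Wnt7b higher and Fgf18 and Fgf15 (2.76-fold) lower among 15. Hba-x (2.02-fold) was lower for erythroid, 1 of 12, Dnajb1 (2.22-fold) for stress, 1 of 8, and Isl1 for sensory ganglion, 1 of 3. Eif2s3y was at least 7.46-fold higher and Xist 2.43-fold lower, and midbrain and hindbrain, endothelium, muscle and heart, proliferation, macrophage and notochord genes had 0 counted. As deposited, 673 of 1150 eligible genes differed, 146 higher and 527 lower (21.7% higher), and relative to the median gene, after a log2 shift of -0.19, 169 and 457 (27.0% higher).

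Neural epithelium of E10.5 as a class (3 libraries) was compared with the nasal prominences and arches (4 libraries) to ask what separates brain from face. With all 7 libraries limma found 0 of 10184 genes past the threshold, with 786 at an unadjusted p under 0.05 where 509.2 were due by chance, and 0 and 1048 relative to the median gene. The 4 facial libraries include the one labelled medial nasal prominence with its brain genes. Adjusted over the list alone, forebrain genes were higher for 5 of 7 tested, erythroid genes lower for 7 of 8, facial mesenchyme genes lower for 5 of 12, cranial mesoderm genes lower for 3 of 4, endothelium genes lower for 3 of 6, olfactory placode genes higher for 4 and lower for 2 of 12, matrix genes lower for 2 of 8 and neural crest genes lower for 1 of 8, against 0 over all genes for each of these lists. Relative to the median gene these counts were 5, 5, 0, 3, 3, 0 and 0, 0 and 0, with 2 of 9 neural progenitor genes higher. The other 16 lists with 3 or more members above the floor had 0 members adjusted over the list alone. In the exact permutation of labels over 25 lists the smallest p was 0.0286, the smallest that 35 relabelings can give, for the endothelium list as deposited, with a mean log2 difference of -0.87 and an adjusted p of 0.268.

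Without the library labelled medial nasal prominence, a fit planned as 1 of 7 that leave out a library and described in full after the data were seen, 3 libraries stood against 3 and limma found 1093 of 9512 genes past the threshold, 910 higher and 183 lower (83.3% higher). The library left out was doubted for its high brain genes and low face genes. Counts and p-values for such genes without it are therefore no independent evidence. Fits that left out another library gave 2 genes at most. The log2 shift between the classes was 0.45, and relative to the median gene 247 rose and 338 fell (42.2% higher), of which 429 were shared with the count as deposited. In brain, forebrain genes rose for 4 of 7 tested, with Otx2 at 4.73 ± 0.53 (log2 fold change ± SE, n = 3 against 3 libraries, adjusted p = 0.00283 with limma) and Lhx2 at least 14.5-fold, and neural progenitor genes for 5 of 8, with Nes at 3.37 ± 0.34, Sox2 at least 7.02-fold and Sox21 at least 5.76-fold. Where each library of a class was at the floor, the fold is the lowest library of the other class over that floor, written "at least". Ckb, the brain creatine kinase, rose at least 13.9-fold and the nuclear receptor Nr2e1 at least 4.86-fold. In face, facial mesenchyme genes were the largest group, and 9 of 12 fell in neural epithelium, with Prrx1 at -5.65 ± 0.46, Twist1 at least 27.8-fold lower (adjusted p = 0.000407 with limma) and Msx1 at least 7.01-fold lower.

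Other genes of the face also fell in neural epithelium, with matrix genes for 4 of 7 (Col1a2 at -5.11 ± 0.40, Col3a1 at least 18.5-fold lower), nasal prominence genes for 5 of 6 (Eya1 at least 6.58-fold lower), neural crest genes for 4 of 8 (Crabp1 at -5.01 ± 0.89, Snai2 at -3.34 ± 0.24) and cranial mesoderm genes for 3 of 4. Igf1 at -5.73 ± 1.19, Igf2 at -4.68 ± 0.88 and Ednra, the endothelin receptor of the crest, at least 15.4-fold lower, were among the largest. Blood and vessel genes fell with them, erythroid for 8 of 8 (Hbb-bh1 at -4.70 ± 0.69) and endothelium for 3 of 6 (Emcn at least 5.49-fold lower). Olfactory placode genes rose for 4 and fell for 3 of 12, neuronal genes rose for 2 of 9 (Stmn2 at least 3.37-fold, Ina at least 1.96-fold) and Sox6 (at least 3.48-fold) for chondrogenic genes, 1 of 6. Adjusted over the list alone the counts were 5 for forebrain, 6 for neural progenitor, 10 for facial mesenchyme, 5 for matrix, 6 for nasal prominence, 5 for neural crest, 4 for cranial mesoderm, 8 for erythroid, 4 for endothelium, 5 and 3 for olfactory placode, 6 higher and 1 lower for neuronal and 1 for chondrogenic genes, in the directions given. Hedgehog targets (1 higher), dorsal neural (1 higher), ventral telencephalon (2 higher) and secreted ligands (1 higher and 2 lower) had members past the threshold only so, against 0 over all genes, and floor plate, midbrain and hindbrain, distal arch, surface epithelium, heterochronic, proliferation, stress and sex-linked genes had 0 either way. With 3 libraries against 3, the exact permutation test cannot go below p = 0.1, which 13 of 25 lists reached.

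**Figure D5:**
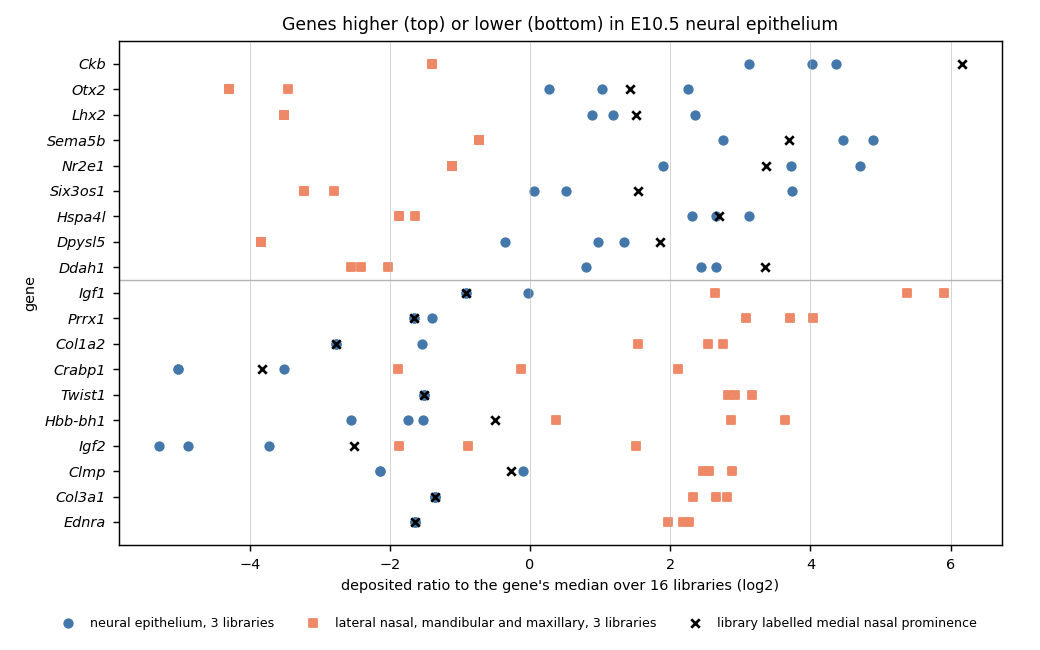
Deposited ratio (log2, relative to the median of each gene over 16 libraries) of named genes higher (top) or lower (bottom) in E10.5 neural epithelium (circles, 3 libraries) than in the lateral nasal, mandibular and maxillary libraries (squares, 3 libraries), with the library labelled medial nasal prominence as crosses. The crosses lie with or beyond the neural libraries for Prrx1, Twist1 and Ckb, and facial libraries at the floor overlap.

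Neural epithelium was last compared between E10.5 and E8.5, with 3 libraries in each class, and all 3 of E10.5 are among the 6 with lower values. Heterochronic genes fell for 4 of 7 members relative to the median gene and 5 as deposited, with Lin28a at -4.12 ± 0.45 (log2 fold change ± SE, n = 3 and 3 libraries, adjusted p = 0.00334 with limma), Trim71 at -3.33 ± 0.32, Hmga1 at -1.53 ± 0.25 and Lin28b at -1.05 ± 0.27. The fifth as deposited was Igf2bp1, at -1.28 ± 0.28 there and -0.93 ± 0.22 relative to the median gene. Neuronal genes rose for 4 of 9 tested, Elavl4 at 3.18 ± 0.59, Nefm at 3.08 ± 0.40, Dcx at least 2.56-fold and Elavl3 at least 1.98-fold. Ventral telencephalon genes rose for 3 of 6, with Olig2 at least 6.87-fold and Dlx1 at least 2.28-fold, and the glial and progenitor genes Sox9 (3.11 ± 0.66), Sox6 (2.70 ± 0.47) and Nes (3.97 ± 0.44) rose with them. Vim at 4.79 ± 0.56, Ckb at 5.13 ± 0.68, Nr2e1 at 3.94 ± 1.01, Oxct1 at 3.95 ± 0.27, Bcl11a at least 11.5-fold and St18 at least 14.6-fold were among the largest rises, and Ncrna00085 rose by 5.86 ± 0.35.

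Ifitm2 at -4.71 ± 0.47, the orphan receptor Nr6a1 at -4.06 ± 0.49, the ribosomal gene Rplp2 at -3.92 ± 0.40, Aprt at -3.62 ± 0.22 and 5 ribosomal or chaperone pseudogenes such as Rpl10a-ps1 at -4.59 ± 0.86 were among the largest falls in E10.5 neural epithelium. Over 256 ribosomal and respiratory genes the medians relative to the median gene were -0.83, -1.12 and -1.05 in its 3 libraries, against 0.22, 0.12 and 0.34 in those of E8.5. In the other lists, Olig2 rose as the 1 of 4 hedgehog targets, Nes of 9 neural progenitor genes, Sox9 of 5 neural crest genes, Dlx1 of 1 facial mesenchyme gene, Sox9 and Sox6 of 5 chondrogenic genes, and the globin Hba-a1 (2.56 ± 0.55) of 5 erythroid genes, while Dnajb1 fell (-1.24 ± 0.31) of 2 stress genes. Mki67 (1.03 ± 0.26) and Xist (1.23 ± 0.35) passed relative to the median gene but not as deposited, while Cdk1 (-1.15 ± 0.35), Cdc20 (-1.86 ± 0.48) and Eif2s3y (-2.32 ± 0.70) fell as deposited but did not pass relative to the median gene, as did the olfactory placode gene Six4 (at least 2.05-fold). Adjusted over the list alone the counts relative to the median gene were 3 of 5 chondrogenic and 1 of 1 distal arch genes higher and equal to those over all genes in the other lists. Floor plate, forebrain, midbrain and hindbrain, dorsal neural, maxillary program, nasal prominence, surface epithelium, secreted ligand, matrix, muscle and heart, endothelium and sensory ganglion genes had 0 past the threshold over all genes. As deposited, adjusted over the list alone, 1 of 2 midbrain and hindbrain genes and 1 of 10 proliferation genes fell, and the other lists had the counts they have over all genes.

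In all, 2077 of 10466 genes passed in the neural stage comparison, 310 higher and 1767 lower at E10.5 (14.9% higher), with 3987 at an unadjusted p under 0.05 where 523.3 were due by chance. The log2 shift between the classes was -0.35, and relative to the median gene 721 rose and 975 fell (42.5% higher), of which 1285 were shared with the count as deposited. The classes did not overlap for 4452 genes (42.5%), where chance gives 10%. Without E8.5 caudal brain 1010 genes passed, and 674 in place of 1696 relative to the median gene. The exact permutation test over lists could not go below p = 0.1.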

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

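All tests of the libraries labelled medial nasal prominence, central and dorsal control, the tests of 1 scale factor and of embryonic stage, and the counts over other splits of the libraries were chosen after the results were seen, and those of gene length and GC content before.

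Among the 4 E10.5 nasal prominence and arch libraries, the library labelled medial nasal prominence stood far from the other 3 in 5 of the 27 gene lists that could be compared, and the maxillary arch in 2. Chance alone sets a library apart in about 1 in 20 lists. The mean log2 level of floor plate genes was 1.95 there (0.13 to 0.35 in the other 3), of neural progenitor genes 3.49 (0.11 to 0.29), of neuronal genes 2.51 (0.13 to 0.48), of forebrain genes 2.67 (0.00 to 0.38) and of matrix genes 0.34 (1.73 to 1.92). The maxillary arch stood apart in surface epithelium genes (0.14, against 0.00 to 0.01) and sensory ganglion genes (1.44, against 0.81 to 0.90).

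The library labelled medial nasal prominence had neural genes and lacked mesenchyme genes of the face. Prrx1 and Twist1 argue against a mix with facial mesenchyme. These 2 alone of the list reached 5 times the floor in the other 3 facial libraries, and 0 were above it here. Endothelium genes here (0.67) lay near those libraries (0.775 to 0.872), above the E10.5 neural ones (0 to 0.26). A share of other non-neural tissue stays open. An exchange with another E10.5 neural library is argued against as well. Facial mesenchyme genes had a mean log2 level of at most 0.35 in the 3 neural libraries, against 1.79 or more in the other 3 facial ones. The 0.35, in lateral prominence, came from Dlx1 (8.07) and Dlx2 (4.63) alone. Another tissue or label for the library labelled medial nasal prominence stays open. Its mean of 0.60 came from Dlx1 and Dlx2, also in the ventral telencephalon list. The ventral forebrain genes in this library make brain tissue a candidate source. The tests were made on the lists that drew attention to the library, and no biological explanation was tested.

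The library labelled central had dorsal genes and the library labelled dorsal control ventral genes. The dorsal list was higher in the first and the ventral list higher in the second by 2.58 in log2 when both differences are added. A share of facial mesenchyme is argued against, since its list differed by -0.25. That difference came from Dlx1 (1.92 in the library labelled central, 8.36 in dorsal control) and Dlx2 (1 and 3.54), also ventral genes. Prrx1 was at 1.20 and 1, and the other members were at the floor in both. An exchange of the 2 names may explain the pattern, and the crossed abbreviations in the file names go with it, but which name is right cannot be read from the values. Real differences between the regions, with the names as given, stay open and were not tested.

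Lower values and more genes at the floor marked the 6 E10.5 libraries of the lateral nasal prominence, the arches and the neural epithelium. A single scale factor per library could not be judged by its test. After centring, the 3 facial and 3 neural libraries had a median Spearman correlation of 0.33 across genes (which are not independent replicates). Ranks do not change with centring, so this value would be the same without it. Embryonic stage alone is argued against, because the lower shift of the 2 other E10.5 libraries was 0.21, above 0. A loss that depends on GC content may contribute, since the difference between these 6 and the other 10 libraries had a Spearman correlation of -0.35 with it, with medians relative to the median gene from 0.25 in the fifth of genes with the lowest GC content to -0.42 in the highest. Gene length stays open as well, with a correlation of 0.22, between the limits of 0.1 and 0.3 set for its test, and medians from -0.19 in the fifth with the shortest transcripts to 0.20 in the longest, and it was not separated from GC content. The sources used here give no preparation batch, so a batch shared by the 6 libraries stays open, and so do tissue differences, which were not tested.

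Some genes differed between the arches in opposite directions at the 2 stages. The mandibular over maxillary log2 ratio went from -2.22 at E9.5 to 1.59 at E10.5 for Hbb-y, from -2.18 to 2.46 for Hbb-bh1, from -1.39 to 1.49 for Hba-a1, from -3.33 to 1.97 for Hbb-b2 and from -1.83 to 2.56 for Nr2f1. With 1 library per arch and stage the difference between stages was not tested.

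In the limma comparison of E10.5 neural with facial libraries the real split gave 0 genes, so all 35 splits of the 7 libraries gave as many by construction, and this count says nothing about chance. The highest other split, with the lateral nasal, mandibular and maxillary libraries against the other 4, gave 1424 genes as deposited and 793 relative to the median gene, which points to a structure of the libraries. These 3 libraries also have the lowest shifts (-0.38, -0.70 and -0.82), so the count as deposited does not separate low values from tissue. For E10.5 against E8.5 neural epithelium, 1 of the 10 splits, the real one, gave as many genes as 2077, and the highest other gave 1. With 10 splits no share under 0.05 can be reached.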

How the results depend on the processing

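Removal of the GC trend, counts of never-tied genes at any level, and the total of enriched genes without the library labelled medial nasal prominence were chosen after seeing the data, and the other alternatives were planned. Scaling changed some directions. As deposited, the ratios of Twist1 (-0.14) and Snai2 (-0.071) between stages in the maxillary arch had the opposite sign to those relative to the median gene, and so did 21 of 129 list medians, 0 of them from 1 or more in size (9 and 0 with the GC trend removed). Relative to the median gene, more genes were lower than higher in E8.5 mesoderm (583 against 402) and in the neural against facial fit without the library labelled medial nasal prominence (338 against 247), where more were higher as deposited. Of the counts of genes, 30 stayed within 1.5 times and 37 moved under alternatives planned beforehand, and 20 and 13 under the added ones. Of list medians 83 stayed and 46 moved under those planned beforehand, and 126 and 3 under added ones. Of results for single genes 509 stayed, 216 moved, 14 missed the threshold and 2 reversed under those planned beforehand, and 556 and 17 stayed and moved under added ones. All 50 results of the exact list tests stayed on their side of the threshold, which says nothing about stability for the 25 with 3 libraries against 3, since these could not pass it.

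The level asked of the higher library set the single-library counts, because a lower level admits more genes. At a level of at least 1, the counts were 2386 for floor plate, 1714 for caudal brain, 2783 for mesoderm, 1385 and 1815 for the arches at E9.5 and E10.5, 5416 and 6184 for the mandibular and maxillary arch over stage, 3045 for epidermal ectoderm, 4565 for lateral against medial nasal prominence, 3872 for olfactory pit, 2291 for lateral prominence and 2299 for the library labelled central against the one labelled dorsal control. At a level of at least 20 these were 193, 179, 214, 62, 37, 138, 124, 213, 169, 118, 75 and 75, in the same order. Shared arch genes numbered 81 and 2 at the 2 levels, shared stage differences in both arches 3651 and 71, and enriched genes 22 at the higher.

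With never-tied genes counted at any level, which counts more genes, there were 1437 for floor plate, 1380 for the arches at E10.5, 4182 and 4707 for the mandibular and maxillary arch over stage, 3216 for lateral against medial nasal prominence, 2559 for olfactory pit, 1443 for lateral prominence, 1448 for the library labelled central, 43 shared arch genes and 2867 shared stage differences in both arches. With the GC trend removed the maxillary stage count was 1262, shared stage genes 452 and enriched genes 64, and scaled to the median gene shared stage genes were 592. With the library labelled central in place of dorsal control, the count for lateral prominence was 262. For the GC trend, the scaling and the exchanged library the cause was not tested.

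In limma, neural epithelium of E10.5 against facial libraries gave between 0 and 1093 genes when each library was left out, with 1093 without the library labelled medial nasal prominence, 2 without dorsal control and 0 without any 1 of the other 5. Against E8.5 it gave 1010 to 2307, with 1010 without caudal brain, 1281 without non-floor plate neural epithelium, 1351 without the library labelled central and 2307 without dorsal control, and relative to the median gene 674 to 1666, with 674, 717 and 977 without the first 3 of these, and as deposited 714 with a level of at least 5 in 3 libraries, where fewer genes were tested. Where a class of 3 lost a library, 2 remained. The alternative of a pseudocount of 0.1 was not run, because the values are ratios with a floor. No paired analysis was possible because no label pairs the libraries. Depth was stated only as above 40000000 reads, so what depth limits could not be computed, and the floor hides differences among low values.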

Other observations

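The test of transcript length below was chosen before its result was seen, and the search for genes low in a single library after.

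Of the 109 genes that differed between the arches in opposite directions at E9.5 and E10.5 relative to the median gene, 102 were lower in the mandibular library at E9.5 and higher at E10.5, and 7 the other way. Among them 49 encode ribosomal proteins or respiratory chain subunits, against 14 of the 268 other genes eligible at both stages. Their median transcript length was 569 bases against 1025, a ratio of 0.56. A candidate explanation is therefore a difference in the yield of short transcripts between the libraries, and a difference between the arches in these genes stays open.

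Some genes were low in 1 library alone. In 30 genes the lowest library lay at least 4-fold below the next, in 13 of the 16 libraries, with 6 genes in the E10.5 maxillary arch, 4 in the olfactory pit and 4 in the library labelled dorsal control. Large gaps were those of Cops2 in the olfactory pit (25.8-fold), Usp9x (25.2-fold) and Pbrm1 (22.8-fold) in the maxillary arch, Rnf44 there (16.9-fold) and Tcf7l1 in epidermal ectoderm (14.0-fold).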
